A study of Homo sapiens with 6 samples.

How the data were processed

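Peripheral blood leukocytes of 3 control donors and 3 donors with eosinophilic esophagitis (EoE, a chronic allergic disease in which eosinophils enter the esophagus) were profiled by single-cell RNA sequencing, 1 library per donor. Per the labels' protocols, red cells were depleted, 15000 cells were loaded per HIVE CLX device (cells settle by gravity into picowells that hold barcoded capture beads), and the libraries carry unique molecular identifiers (UMIs), so that each molecule is counted once. The deposited matrices hold whole-number UMI counts per gene symbol and barcode that were not normalized, with 5000 barcodes in each library. The submitters' processing notes name Seurat 4.4.0, R 4.1.3 and the GRCh38 build. The aligner and the gene annotation are not given in the sources used here. All libraries carry 1 batch label, so the labels give no batch to test. Groups and replicate numbers come from the sample titles. Each library is a separate donor, and the donor is the replicate throughout.

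Barcodes were kept with at least 200 UMIs, at least 100 genes and at most 20% of UMIs from mitochondrially encoded genes. Scrublet, run in each library with scanpy 1.11.5, marked between 0 and 4 barcodes per library at its automatic threshold, too few for that threshold to be relied on; whether doublets were rare or the threshold was misplaced was not tested. The 5% of barcodes with the highest Scrublet scores in each library were removed in its place. Doublets can therefore persist among the 17717 kept barcodes. Counts were scaled to 10000 per barcode and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 were computed over all libraries together without integration. Mitochondrial, ribosomal, hemoglobin and immunoglobulin or T-cell receptor variable genes were left out of the clustering, as were XIST, TSIX and Y-linked genes, which were not analysed here. Clusters were named from marker lists fixed before the data were examined. The scoring rule was written after the count files were examined: a mean marker level of at least 0.3 relative to the highest cluster, at least 1.25 times that of the next cell type or a majority among the leading genes, and at least 3 markers detected in 5% of the barcodes. The alternative to the ratio, by leading genes, was added after the clusters were seen, so that the B-like cluster, where plasma-cell markers scored nearly as high, was named. Clusters 2 and 3 of the 14 stayed unnamed.

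UMI counts were summed per library and class, for libraries with at least 10 barcodes of the class. Sums were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood test) and Benjamini-Hochberg adjustment over the genes of the class, with a threshold of 0.05. A log2 fold change is EoE minus control, and its standard error was taken as the size of the log2 fold change over the square root of the quasi-likelihood F. CPM are edgeR's library-size scaled counts (cpm) of the class with TMM factors, and summed CPM and marker sums are scaled to the total UMIs of the class without them. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, for lists with at least 3 tested genes, adjusted over the lists. An estimated correlation was used as an alternative, and no list of the 6 classes passed with it. Where a camera result is given, neutrophil markers are the gene list of mature markers. It differs from the cell type markers used for naming, marker sums and ratios, and holds S100A8, S100A9, MNDA, NAMPT and MME, which those lack. The difference between classes was tested as the interaction of group and class with the donor as a block. Shares were compared by a two-sided exact permutation test, which for 3 against 3 libraries cannot give a p below 0.1. Intervals on shares are exact 95% binomial (Clopper-Pearson) and cover counting error only.

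Alternatives covered the UMI, mitochondrial and doublet limits, the Leiden resolution, clustering of each library on its own, RLE scaling, no filter on low counts, DESeq2 1.42.0, robust fitting, the replicate number as a block and the omission of each library. The named genes were, per class, up to 10 higher and 10 lower genes with the smallest p among those past the threshold whose groups did not overlap, or, where fewer than 10 passed in total, the 10 genes with the smallest p and no overlap, plus members of the lists described that passed after adjustment over the list alone or ranked among the 4 with the highest CPM. From those members, the ones described were chosen after their values were seen. Genes of the X-inactivation centre are not named, and a further gene that the rule gives for monocyte-like cells is not reported. The edgeR test was tested on simulated data drawn from each class with 200 changed genes. It called 44% of 100 genes changed 2-fold and 94% of 100 changed 4-fold among 1382 simulated genes of the eosinophil-like class, 10% and 78% among 5772 of the neutrophil-like class, 44% and 86% among 5652 of the monocyte-like class, 55% and 90% among 6284 of the T-like class, 50% and 91% among 2784 of the NK-like class, 52% and 92% among 1773 of the B-like class, and 28% and 89% among 10525 of all barcodes summed. The interaction test called 35.5% of 200 genes changed 4-fold in simulated data of 3604 genes. Unchanged genes made up 2.8% of the calls in the eosinophil-like, 6.4% in the neutrophil-like, 7.8% in the monocyte-like, 8.8% in the T-like, 4.1% in the NK-like and 7.1% in the B-like class, 4.9% in all barcodes summed and 6.6% in the interaction, where the threshold aims at 5%. Of the lists that were not shifted, camera called 2 of 19 in the neutrophil-like class and 0 in the other classes. The simulated genes were drawn independently of each other, so these counts cannot show how often camera calls lists of correlated genes. Gene positions are from GENCODE 29 on GRCh38. The files pair counts with symbols only, so HLA-DRB1, FCGR3A, FCGR3B, FCGR1A, GZMB and MT-RNR1, which have near-identical copies, are uncertain in how their reads were split.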

Results

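The series asked how blood eosinophils, and the leukocytes around them, differ between donors with EoE and controls. The control libraries held 1539499, 4193016 and 3674751 UMIs and the EoE libraries 2120373, 3416363 and 1306063 UMIs in replicates 1, 2 and 3. After filtering, 1780, 4114 and 3721 control barcodes and 2716, 4074 and 1312 EoE barcodes were kept, with medians of 340.5, 650 and 514 UMIs in control and 338.5, 446 and 335 UMIs in EoE libraries. No pair of libraries held identical sums per gene.

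Clustering separated eosinophil-like cells (402 barcodes, led by PRSS33, CLC, SIGLEC8 and IL5RA), neutrophil-like cells (5597), monocyte-like cells (1495), T-like cells (3421), NK-like cells (805), B-like cells (928), basophil-like cells (405) and platelet-like barcodes (121). A further 4543 barcodes fell in clusters 2 and 3, which did not meet the naming rule. They made up 26.7% ± 19.9 of control and 32.5% ± 17.8 of EoE barcodes (SD, n = 3 each). Eosinophil-like cells carried abundant CLC, the Charcot-Leyden crystal protein, at 4484 summed CPM ± 1376 (SD, n = 6), against 69.8 ± 54.0 in neutrophil-like cells. RNASE2, a granule ribonuclease, stood at 618 ± 524, and the receptor of the alarmin IL-33, IL1RL1, at 186 ± 111 against 2.20 ± 2.10 in neutrophil-like cells. Transcripts of other granule proteins were scarce: RNASE3 gave 15 UMIs over all eosinophil-like cells, PRG2 gave 2 and EPX gave 0. CLC and RNASE2 are among the markers that name the class, so their level there is not an independent result.

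Eosinophil-like cells made up 2.40% ± 1.35 of barcodes in control and 1.65% ± 0.95 in EoE libraries (SD, n = 3 each; exact permutation p = 0.5). Single libraries ranged from 0.762% (95% interval 0.366 to 1.40) in EoE replicate 3 to 3.76% (3.17 to 4.42) in control replicate 3. The difference of -0.751 percentage points was -0.0716 without control replicate 3, -0.305 without EoE replicate 3, -1.42 without control replicate 1 and -1.25 without EoE replicate 1. It was -0.445 at 400 UMIs or more and -0.460 with no mitochondrial limit. Monocyte-like cells were lower in every EoE library than in every control library, at 6.22% ± 0.77 against 9.74% ± 1.54 (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The difference of -3.51 points was -0.963 at 400 UMIs or more, -2.09 at a Leiden resolution of 0.5 and -2.33 with no mitochondrial limit. It was -5.27 at Scrublet's automatic threshold and -2.66 with no barcode removed as a doublet, settings that differ by 0 to 4 barcodes per library. It turned to 0.937 with each library clustered on its own. Unnamed cluster 2 (3623 barcodes, median 297 UMIs) was led by LYZ, a monocyte marker, with HLA-DRA and FCN1 also among its leading genes. Monocyte-like barcodes had a median of 1000 UMIs. Cluster 2 held 46.4%, 8.14% and 20.4% of control and 11.4%, 19.9% and 44.4% of EoE replicates 1, 2 and 3. Whether it holds shallow monocytes was not tested, so the monocyte-like share covers the named barcodes only. T-like cells made up 9.56% ± 5.45 in EoE and 24.3% ± 12.7 in control libraries (exact permutation p = 0.2). This difference of -14.7 points was -7.49 without control replicate 2, -2.54 at 400 UMIs or more and -8.47 with each library clustered on its own, where no barcode of EoE replicate 1 was named T-like. NK-like cells made up 3.34% ± 1.90 and 5.10% ± 1.04 (exact permutation p = 0.3). Their difference of -1.76 points was -0.809 without EoE replicate 1, -2.71 without EoE replicate 2 and -1.16 without control replicate 2. It was -4.24 with each library clustered on its own, where no barcode of EoE replicates 1 and 3 was named NK-like, and -3.04 at Scrublet's automatic threshold, -2.92 at 400 UMIs or more and -1.02 at a Leiden resolution of 0.5. Neutrophil-like cells averaged 38.3% ± 26.7 in EoE and 23.4% ± 6.6 in control libraries (exact permutation p = 0.6). That difference rested on EoE replicate 1, where they reached 68.8% (67.0 to 70.5), and the difference of 14.9 points turned to -0.35 without that library and was 24.5 without EoE replicate 3, 7.63 with each library clustered on its own and 9.48 at 100 UMIs and 50 genes or more. B-like cells made up 5.91% ± 4.64 and 5.37% ± 2.26 (exact permutation p = 0.9), and their difference of 0.54 points turned negative without control replicate 3 (-0.41) or EoE replicate 3 (-2.03). It was 2.48 without EoE replicate 1, 1.17 without EoE replicate 2, 0.242 without control replicate 1 and 1.79 without control replicate 2. Under the alternatives on filters, doublets, clustering and denominator it ran from 0.133 with no barcode removed as a doublet to 2.97 over named leukocytes. No share passed a test at 0.05, which this design cannot reach. The shares depend on the UMI and gene limits, which between 1607 barcodes in EoE replicate 3 and 4996 in control replicate 2 passed. Each matrix held 5000 barcodes, and 4893 passed in control replicate 3 and 4866 in EoE replicate 2. Lower limits can therefore add few barcodes to these libraries and to control replicate 2. Whether shallower barcodes were left out of their matrices was not tested.

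**Figure D1:**
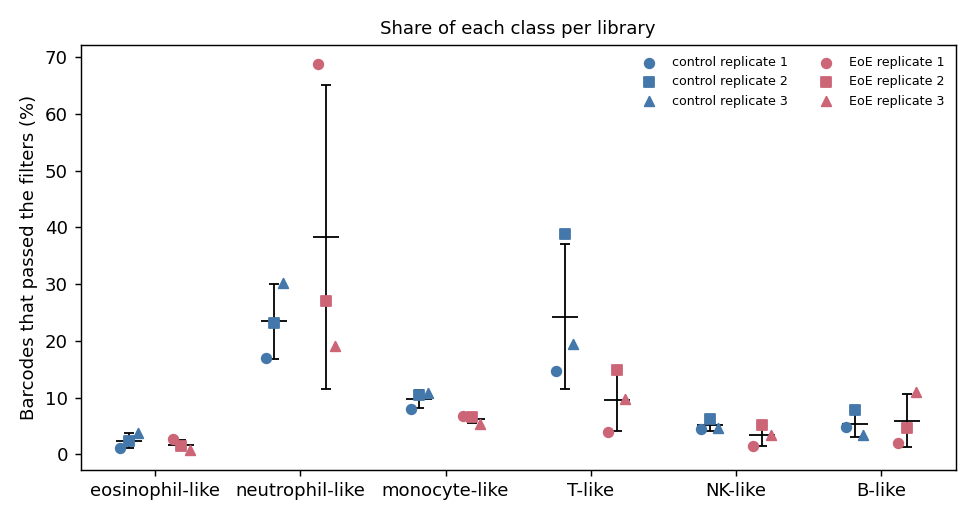
Share of the barcodes that passed the filters (y axis, percent) in each of the 6 tested classes (x axis), for control (blue) and EoE (red) libraries. Points are libraries, black dashes are group means and bars are the SD over 3 libraries. All 3 EoE libraries lie below all 3 control libraries for monocyte-like cells, and EoE replicate 1 stands at 68.8% for neutrophil-like cells.

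In eosinophil-like cells no gene passed the edgeR quasi-likelihood test between EoE and control (0 of 1382 genes, with 62 at an unadjusted p under 0.05, and 0 with DESeq2). The sums per library ran from 6058 UMIs, in the 10 barcodes of EoE replicate 3, to 118756 UMIs. The groups did not overlap for 9.33% of these genes, where chance gives 10%. The genes named next had the smallest p among those whose groups did not overlap, and none passed the threshold. Their separation follows from that choice. They included HK3, a hexokinase of myeloid cells (chromosome 5, 176880869 to 176899332). It stood at 44.4 CPM ± 38.6 in control and 352 ± 71.6 in EoE libraries (log2 fold change 2.35, SE 0.61, adjusted p = 0.618). ZNF638, ZNF655 and BACE2 were also higher, with log2 fold changes of 1.17, 1.71 and 1.93. SNX14, IL7R, MSL1, RPL31, LYZ and MNDA were lower, with log2 fold changes from -1.98 for SNX14 to -1.04 for MNDA. IL7R is a T-cell marker and LYZ a monocyte marker. T-cell markers summed to 261 CPM ± 266 in the EoE and 715 ± 200 in the control eosinophil-like cells, and monocyte markers to 2202 ± 407 and 3229 ± 1462.

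Among the fixed gene lists, 5 passed in eosinophil-like cells at the preset correlation. Cytosolic ribosomal proteins were lower for 39 of 44 genes (median log2 fold change -0.43, camera adjusted p = 1.97e-07), with 0 passing over all genes and 0 adjusted over the list alone. RPS6 stood at 997 CPM ± 374 in EoE and 1686 ± 586 in control libraries. Interferon-response genes were higher for 8 of 9 (median 0.69, adjusted p = 0.00106), with 0 passing either way. XAF1 and IFIT3 had log2 fold changes of 0.80 and 0.92. Glycolysis genes were higher for 4 of 4 (median 0.48, adjusted p = 0.0134), with HK3 alone past the threshold adjusted over the list alone and HK2 at 475 CPM ± 67.5 against 298 ± 42.4. The list of the IL-5, GM-CSF and IL-3 response, cytokines that prolong eosinophil survival, was higher for 6 of 7 genes (median 0.59, adjusted p = 0.0485), with 0 passing either way. BCL2A1, an anti-apoptotic protein, stood at 840 CPM ± 268 in EoE and 467 ± 114 in control libraries, and the shared receptor chain CSF2RB had a log2 fold change of -0.14. Neutrophil markers were lower for 6 of 7 genes (median -0.17, adjusted p = 0.0485), with MNDA past the threshold adjusted over the list alone. None of these calls held with an estimated correlation (adjusted p = 0.643 for 4 lists and 0.683 for neutrophil markers).

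Single libraries decided several of these eosinophil lists. Without EoE replicate 1 the interferon median was -0.29 (adjusted p = 0.983). The IL-5, GM-CSF and IL-3 list lost its call without control replicate 2 (0.112), control replicate 3 (0.172), EoE replicate 1 (0.0862) or EoE replicate 2 (0.454). Glycolysis lost it without control replicate 2 (0.191), control replicate 3 (0.147), EoE replicate 1 (0.293) or EoE replicate 2 (0.336). Neutrophil markers lost it without control replicate 1 (0.227), control replicate 2 (0.634) or EoE replicate 3 (0.875), and ribosomal proteins without control replicate 2 (0.112). With RLE scaling, an alternative chosen after the data were seen, the IL-5, GM-CSF and IL-3 list and neutrophil markers had an adjusted p of 0.0502. Neutrophil markers lost the call under all 8 alternatives on filters, doublets and clustering (adjusted p from 0.34 to 0.891). The IL-5, GM-CSF and IL-3 list lost it under 5 of them (0.437 with no barcode removed as a doublet, 0.252 at Scrublet's automatic threshold, 0.149 at a Leiden resolution of 2.0, 0.313 with no mitochondrial limit and 0.333 at 100 UMIs and 50 genes or more). With no barcode removed as a doublet, glycolysis (0.0552) and ribosomal proteins (0.0603) lost it too. With each library clustered on its own, no barcode of control replicate 1 or EoE replicate 3 was named eosinophil-like. Those libraries did not enter the tests of this class in that setting. Eosinophil surface receptors (3 of 7 higher, median -0.14, adjusted p = 0.694) and type 2 cytokine signalling genes (1 of 3 higher, median -0.36, adjusted p = 0.585) did not pass. The receptor CCR3 stood at 931 summed CPM ± 113 in control and 636 ± 132 in EoE libraries, CYSLTR2 at 572 ± 46.5 and 282 ± 102, and ALOX15, which makes lipid mediators, at 156 ± 135 and 446 ± 268. These 3 were chosen after their values were seen, and CCR3 and ALOX15 are markers that name the class.

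In neutrophil-like cells 0 of 5772 genes passed (249 at an unadjusted p under 0.05, and 0 with DESeq2), on 190735 to 996892 UMIs per library. The groups did not overlap for 9.15% of genes, where chance gives 10%. Among genes whose groups did not overlap, those with the smallest p, none past the threshold, were the class II antigen gene HLA-DQB1 (8.80 CPM ± 3.08 in control and 50.8 ± 5.35 in EoE libraries, adjusted p = 0.289), the Fc receptor chain FCER1G (368 ± 79.1 and 783 ± 91.3, adjusted p = 0.979) and GPR65 (87.4 ± 9.11 and 182 ± 34.1). SBNO2, FOSB, PAXBP1 and HLA-DRB1 higher and LUC7L3, CHURC1 and SLF1 lower in EoE libraries were the others.

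The interferon-response list was higher in neutrophil-like cells for 23 of 24 genes (median log2 fold change 0.85, camera adjusted p = 3.9e-05, adjusted p = 0.733 with an estimated correlation), with 0 genes past the threshold over all genes and 0 adjusted over the list alone. The summed list stood at 16270 CPM in EoE replicate 1, against 4940 and 4063 in the other EoE libraries and 4465 to 5368 in the controls. Without EoE replicate 1 the median was -0.01 (adjusted p = 0.167). That library also supplied 1495 of the 1828 barcodes of cluster 5 and 294 of the 367 of cluster 12, neutrophil-like clusters led by RSAD2 and other interferon-induced genes, while clusters 7 and 8, led by CXCL8, CXCR2 and MME, held most neutrophil-like barcodes of the other libraries. B-cell markers summed to 274 CPM ± 70.0 in EoE and 196 ± 58.2 in control neutrophil-like cells, highest in EoE replicate 1 (343), monocyte markers to 2950 ± 348 and 3601 ± 69.8, and NK-cell markers to 1614 ± 40.3 and 1887 ± 5.23. Class II presentation genes were higher for 8 of 8 (median 0.89, adjusted p = 0.0193, adjusted p = 0.733 with an estimated correlation), and the median was -0.05 without EoE replicate 1 (0.776). The call was also lost without control replicate 3 (0.0595), with no mitochondrial limit (0.09) and with each library clustered on its own (0.229). Immediate early genes were higher for 13 of 15 (median 0.41, adjusted p = 0.00962, adjusted p = 0.733 with an estimated correlation), with FOSB past the threshold adjusted over the list alone, and lost the call without control replicate 2 (0.0654) or EoE replicate 2 (median -0.16, 0.525). Glycolysis genes were higher for 10 of 12 (median 0.46, adjusted p = 0.00938, adjusted p = 0.733 with an estimated correlation), and lost it without EoE replicate 1 (0.0726) or EoE replicate 2 (0.0596). For the last list, SLC2A3, a glucose transporter, stood at 560 CPM ± 153 in EoE and 413 ± 82.4 in control libraries.

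**Figure D2:**
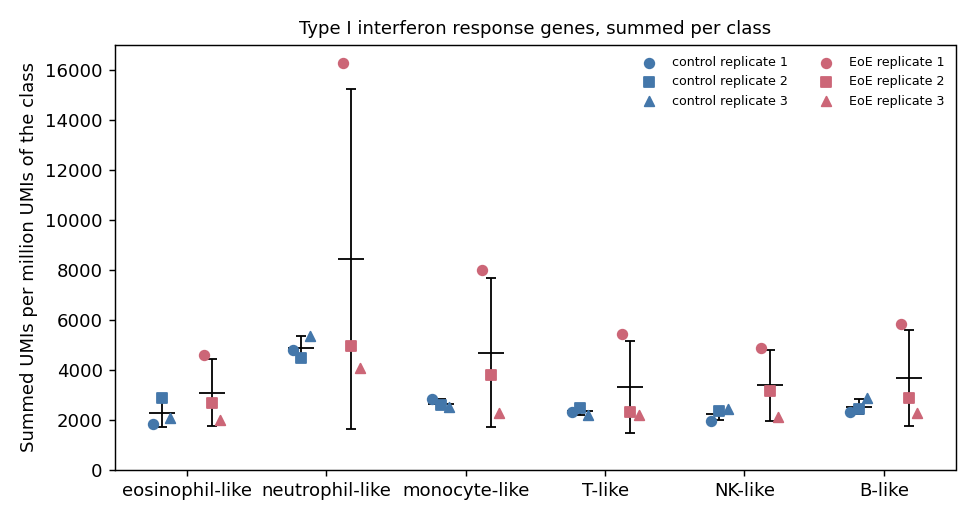
Summed CPM of the type I interferon response list within each class (y axis, scaled to the total UMIs of the class) in the 6 classes (x axis), for control (blue) and EoE (red) libraries. Points are libraries, black dashes are group means and bars are the SD over 3 libraries. EoE replicate 1 is the highest library in each class, at 16270 in neutrophil-like cells.

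Monocyte-like cells from EoE blood expressed more HLA-DQB1 (chromosome 6, 32659467 to 32668383), which stood at 483 CPM ± 309 in EoE and 72.0 ± 17.2 in control libraries (log2 fold change 2.91, SE 0.37, adjusted p = 0.00453, higher in 3 of 3 EoE libraries than in any control library). It was the only 1 of 5652 genes to pass (317 at an unadjusted p under 0.05, and 3 with DESeq2). The groups did not overlap for 10.97% of genes, where chance gives 10%. The count was 0 without control replicate 1 or control replicate 2, 2 without control replicate 3 (HLA-DQB1 not among them), 11 without EoE replicate 1, 15 without EoE replicate 2 and 2 without EoE replicate 3, and 0 with robust fitting. HLA-DQB1 differs in sequence between people, which can change how many of its reads match a reference. Further genes, none past the threshold, were HLA-DRB1, the interferon-induced PLSCR1 (103 CPM ± 7.29 and 244 ± 51.8), the inflammatory cytokine IL1B (21.5 ± 10.6 and 89.7 ± 63.2), and PDK4 higher and IL7R, SYNE1 and IKZF3 lower in EoE libraries. T-cell markers summed to 194 CPM ± 97.1 in EoE and 634 ± 275 in control monocyte-like cells.

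In the same cells, 23 of 23 interferon-response genes were higher (median 0.94, camera adjusted p = 1.3e-13, adjusted p = 0.418 with an estimated correlation). Of these, 0 passed over all genes and 10 rose when adjusted over the list alone, among them XAF1, OAS3, IFI44L and HERC5 (log2 fold changes 0.89, 1.35, 1.36 and 1.42). Without EoE replicate 1 the median was 0.33 (adjusted p = 0.00778). The summed list stood at 7999 CPM in EoE replicate 1, 3790 in EoE replicate 2 and 2275 in EoE replicate 3, against 2491 to 2832 in the controls. EoE replicate 3 thus lay below every control library. Class II presentation genes, a list without HLA-DQB1, were higher for 8 of 8 (median 0.59, adjusted p = 3.79e-07, adjusted p = 0.385 with an estimated correlation), and 6 rose adjusted over the list alone, including CD74 (3114 CPM ± 704 in EoE and 2062 ± 133 in control libraries) and HLA-DRA (1678 ± 362 and 1151 ± 140). Immediate early genes were higher for 14 of 14 (median 0.81, adjusted p = 0.000143, adjusted p = 0.61 with an estimated correlation), with FOSB past the threshold adjusted over the list alone, but the median was -0.03 without EoE replicate 2 (0.163). Eicosanoid genes (6 of 10 higher, adjusted p = 0.0143, adjusted p = 0.385 with an estimated correlation) included PTGS2, the inducible cyclooxygenase, and the prostaglandin receptor PTGER4, which rose adjusted over the list alone (log2 fold changes 2.52 and 1.00). That list lost its call without control replicate 1 (0.0727), control replicate 3 (0.0956) or EoE replicate 2 (0.106), and at Scrublet's automatic threshold (0.0699). Granulocyte activation genes (6 of 8 higher, adjusted p = 0.0277, adjusted p = 0.418 with an estimated correlation) had FCGR1A past the threshold adjusted over the list alone. They lost the call without control replicate 2 (0.0919), control replicate 3 (0.0612), EoE replicate 1 (0.193) or EoE replicate 2 (0.0588), and at 400 UMIs or more (0.0534). Ribosomal proteins were lower for 64 of 72 (median -0.18, adjusted p = 5.72e-06, adjusted p = 0.67 with an estimated correlation).

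T-like cells gave the largest count of the 6 classes, with 1 gene higher and 16 lower in EoE libraries among 6284 tested (698 at an unadjusted p under 0.05, and 31 with DESeq2, of which 14 were shared). The groups did not overlap for 17.0% of genes, where chance gives 10%. The proliferation marker MKI67 rose from 11.7 CPM ± 5.87 to 54.0 ± 35.6 (log2 fold change 2.28, SE 0.43, adjusted p = 0.0161). The lower genes were mostly transcripts of monocytes and neutrophils. Lysozyme (LYZ) fell from 2170 CPM ± 655 to 764 ± 161 (log2 fold change -1.49, SE 0.21, adjusted p = 0.00359), VCAN from 280 ± 64.8 to 101.4 ± 3.42 (adjusted p = 0.0064), FCN1 from 406 ± 58.8 to 178 ± 17.4 and FCGR3B from 806 ± 244 to 345 ± 45.4 (adjusted p = 0.00973). LRRK2, OGFRL1, PTAFR, CTSS, CENPK, MNDA, ABHD5, AIF1, FCGR3A, LUCAT1, SNX10 and TNFAIP2 were the others. Monocyte markers summed to 1176 CPM ± 152 in EoE and 3096 ± 798 in control T-like cells, neutrophil markers to 1780 ± 185 and 3382 ± 937, and T-cell markers to 6246 ± 224 and 5658 ± 789. The deeper T-like cluster, led by TCF7, LEF1 and CCR7, held 30.8% ± 3.20 of T-like barcodes in EoE and 16.7% ± 8.63 in control libraries (SD, n = 3 each; exact permutation p = 0.1, a comparison chosen after the data were seen). The count was 9, 1 and 132 without control replicates 1, 2 and 3, 9 without EoE replicate 2, of which 5 were among the 17, and 7 without EoE replicate 3. It was 5 at 400 UMIs or more and 5 with each library clustered on its own, of which 2 were among the 17. In the deeper of the 2 T-like clusters alone, chosen after the data were seen, it was 2. In the larger cluster alone 0 of 4150 genes were called lower, and DESeq2 called 0. Whether the count over both follows from the mix of the 2 clusters was not tested.

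Of the lists in T-like cells, neutrophil markers (the gene list of mature markers) were lower for 13 of 13 genes (median -0.79, camera adjusted p = 2.81e-14, adjusted p = 0.327 with an estimated correlation). Of these, 2 fell over all genes and 10 adjusted over the list alone, including CSF3R, MME and CXCR2. Cytotoxic effectors were lower for 9 of 11 (median -0.72, adjusted p = 1.92e-05, adjusted p = 0.327 with an estimated correlation), and 5 fell adjusted over the list alone, including the granzyme GZMA (57.3 CPM ± 30.6 in EoE and 158 ± 19.7 in control libraries) and NKG7. NK-cell markers summed to 534 CPM ± 154 and 1011 ± 297 in these cells. Ribosomal proteins were higher for 72 of 74 (median 0.38, adjusted p = 3.15e-17, adjusted p = 0.347 with an estimated correlation). The chemokine receptor of naive T cells CCR7, a leading gene of the deeper T-like cluster, rose adjusted over its list alone (log2 fold change 0.82), while C5AR1 and PTAFR fell, and this chemotaxis list was lower for 14 of 20 genes (adjusted p = 0.00789, adjusted p = 0.327 with an estimated correlation). Proliferation genes were higher for 5 of 6 (median 0.53, adjusted p = 0.00789, adjusted p = 0.327 with an estimated correlation), with MKI67, PCNA and STMN1 past the threshold adjusted over the list alone, and lost the call without control replicate 2 (0.405), control replicate 3 (0.407) or EoE replicate 2 (0.553). Immediate early genes (9 of 11 lower, adjusted p = 0.000329, adjusted p = 0.347 with an estimated correlation), class II genes (6 of 6 lower, adjusted p = 0.00476, adjusted p = 0.347 with an estimated correlation) and NADPH oxidase genes (8 of 12 lower, adjusted p = 0.035, adjusted p = 0.327 with an estimated correlation) were lower too. Of these 8 lists, neutrophil markers and ribosomal proteins alone passed at 400 UMIs or more (adjusted p = 4.14e-07 and 9.54e-10) and in the deeper T-like cluster (0.0101 and 2.15e-08). At 400 UMIs or more the adjusted p was 0.543 for cytotoxic effectors, 0.672 for chemotaxis, 0.317 for proliferation, 0.11 for immediate early genes, 0.119 for class II genes and 0.0803 for NADPH oxidase genes. The log2 fold change of S100A9 in T-like cells, a neutrophil marker of the list, was -0.58 and turned to 0.90 with each library clustered on its own. In that setting neutrophil markers (0.732), chemotaxis (0.789), class II (0.885) and NADPH oxidase genes (0.643) lost the call. Immediate early genes passed there in the other direction (0.0152). Class II genes lost the call without control replicate 2 (0.0564), and NADPH oxidase genes without control replicate 2 (0.22), control replicate 3 (0.061) or EoE replicate 2 (0.233).

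NK-like cells from EoE blood expressed more granulysin (GNLY, chromosome 2, 85685175 to 85698854), a cytotoxic granule protein, at 3788 CPM ± 707 against 2052 ± 628 (log2 fold change 0.91, SE 0.16, adjusted p = 0.00181). CD300A rose from 102 CPM ± 77.6 to 323 ± 32.1. CHST2, the interferon-induced XAF1 and the mitochondrial ribosomal RNA MT-RNR1 also rose (log2 fold changes 1.39, 1.03 and 0.53), the last pair with overlapping groups. The T-cell receptor chain CD3G fell from 473 CPM ± 130 to 162 ± 21.0 (adjusted p = 0.0132) and LYZ from 1388 ± 142 to 779 ± 142 (adjusted p = 0.0496). These were 7 of 2784 genes (131 at an unadjusted p under 0.05, and 1 with DESeq2), and the groups did not overlap for 10.2% of genes, where chance gives 10%. RSRP1, GRAP2, CD84 and WWC3 lower and GAS7 higher did not pass. GNLY is a marker that names the class. NK-cell markers summed to 9496 CPM ± 1605 in EoE and 6990 ± 946 in control NK-like cells, T-cell markers to 2371 ± 512 and 2843 ± 274, and monocyte markers to 1073 ± 149 and 1728 ± 58.8. The count was 0 without control replicate 1 or control replicate 2, 12 without control replicate 3, 4 without EoE replicate 1 and 3 without EoE replicate 2, of which 6, 2 and 0 were among the 7. It was 0 with no mitochondrial limit or at a Leiden resolution of 0.5. Cytotoxic effectors were higher for 7 of 11 genes (median 0.24, camera adjusted p = 0.0072, adjusted p = 0.364 with an estimated correlation), of which 1 rose over all genes and 3, GNLY, PRF1 and KLRD1, adjusted over the list alone. The call was lost without control replicate 1 (0.314), EoE replicate 2 (0.111) or EoE replicate 3 (0.079), and at a Leiden resolution of 0.5 (0.0523). Interferon-response genes were higher for 7 of 8 (median 0.60, adjusted p = 0.00169, adjusted p = 0.364 with an estimated correlation), with a median of 0.39 without EoE replicate 1 (0.0448). Neutrophil markers were lower for 6 of 8 (median -0.29, adjusted p = 0.0072, adjusted p = 0.364 with an estimated correlation), which did not hold without control replicate 2 (0.0581) or EoE replicate 3 (0.23), or at a Leiden resolution of 2.0 (0.225).

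In B-like cells 0 of 1773 genes passed (106 at an unadjusted p under 0.05, and 0 with DESeq2), and the groups did not overlap for 12.9%, where chance gives 10%. The count was 10 without control replicate 3, 1 without EoE replicate 1 and 4 without EoE replicate 2. Among genes whose groups did not overlap, those with the smallest p, none past the threshold, included HLA-DQB1 (692 CPM ± 177 in EoE and 180 ± 150 in control libraries, adjusted p = 0.0932), TCL1A, a gene of naive B cells (500 ± 243 and 108 ± 44.8, adjusted p = 0.157), IGHM, BTG2, PLEKHA2 and SMC6 higher and IL7R, CD302, LYZ and STEAP4 lower. TCL1A and IGHM are markers that name the class. B-cell markers summed to 8568 CPM ± 1802 in EoE and 5030 ± 1401 in control B-like cells, monocyte markers to 2744 ± 106 and 4669 ± 912, and T-cell markers to 771 ± 410 and 1842 ± 418. Class II presentation genes were higher for 7 of 7 (median 0.60, camera adjusted p = 4.44e-05, adjusted p = 0.414 with an estimated correlation), and CD74, HLA-DRA and HLA-DMB rose adjusted over the list alone. Interferon-response genes were higher for 10 of 10 (median 0.36, adjusted p = 0.0205, adjusted p = 0.912 with an estimated correlation), with a median of 0.17 without EoE replicate 1 (0.567). There was also no call without control replicate 2 (0.0713), at 400 UMIs or more (0.43), at 100 UMIs and 50 genes or more (0.121), with no barcode removed as a doublet (0.0654) or at Scrublet's automatic threshold (0.0683). Chemotaxis genes were lower for 7 of 10 (median -0.37, adjusted p = 0.0415, adjusted p = 0.414 with an estimated correlation), among them the integrin ITGA4 (log2 fold change -0.83). The call was lost without control replicate 1 (0.972), control replicate 2 (0.0713), EoE replicate 1 (0.134) or EoE replicate 3 (0.483), and under all 8 alternatives on filters, doublets and clustering (adjusted p from 0.121 to 0.983).

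Summed over all kept barcodes, HLA-DQB1 rose from 30.6 CPM ± 5.77 to 166 ± 59.4 (log2 fold change 2.48, adjusted p = 0.0389) and the centromere protein CENPK (chromosome 5, 65517766 to 65563171) fell from 34.6 ± 5.33 to 8.59 ± 0.38 (log2 fold change -2.02, adjusted p = 0.0389), the only 2 of 10525 genes to pass (632 at an unadjusted p under 0.05, and 6 with DESeq2), while the groups did not overlap for 11.2%, where chance gives 10%. The count was 0 without any 1 of the control libraries or without EoE replicate 3, 6 without EoE replicate 1 and 1 without EoE replicate 2, and it was 0 with no mitochondrial limit. FADS2, SLC11A1, DSP, FAM20A, HIF3A, MAPK10, PLEKHS1 and HLA-DRB1 were higher and did not pass. These sums mix expression with the shares of the classes.

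The EoE difference was compared directly between eosinophil-like and neutrophil-like cells of the same donors. It differed for 2 of 3604 genes (144 at an unadjusted p under 0.05), and for both it was lower in eosinophil-like cells. C1ORF162 (chromosome 1, 111473792 to 111478512) had a log2 fold change of -1.08 in eosinophil-like and 1.12 in neutrophil-like cells (difference -2.41, SE 0.55, adjusted p = 0.0379). P2RY14, a receptor of UDP-sugars (chromosome 3, 151212117 to 151278467), had 0.22 and 2.38 (difference -1.97, SE 0.46, adjusted p = 0.0379). P2RY14 is among the 10 leading genes of neutrophil-like clusters 5 and 12, of which EoE replicate 1 supplied 1495 of 1828 and 294 of 367 barcodes. The count was 0 without any 1 of the controls or without EoE replicate 1, and 5 without EoE replicate 2. It was also 0 at 400 UMIs, with no mitochondrial limit, with no filter on low counts, with each alternative on doublets or the Leiden resolution, and with each library clustered on its own. The log2 fold changes per class come from separate fits, so their difference departs from that of the joint fit.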

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

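In this part the tests of myeloid RNA in lymphoid barcodes, of shallow T-like barcodes, of a single EoE library and of donor variants, and the counts over splits, were chosen after the result was seen. The test of neutrophil RNA in monocyte-like barcodes was chosen before and limited to EoE replicate 1 after, and the interaction test and the alternatives by library and UMI limit were planned. The EoE difference of C1ORF162 differed between eosinophil-like and neutrophil-like cells by -2.41 (log2, interaction test), and that of P2RY14 by -1.97, and without EoE replicate 1 the count of such genes was 0. Unnamed cluster 3, led by MUC3A, EGR1, PTGS2 and G0S2, was tested on its own in no comparison and held 16.32% of the barcodes of EoE replicate 2, above the 1.70% ± 0.49 of the control libraries (SD, n = 3). It held 1.80% in EoE replicate 1 and 3.73% in EoE replicate 3.

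Transcripts of monocytes and neutrophils were lower in EoE T-like cells. Shallow barcodes of the larger T-like cluster stay open: 0 of 4150 genes were called lower in that cluster alone (edgeR, 415 at an unadjusted p under 0.05, and 0 called by DESeq2), which leaves no genes called there to measure in the deeper cluster. The neutrophil marker list, fixed before the data were examined, was lower in the deeper cluster (camera adjusted p = 0.0101) and at 400 UMIs or more (4.14e-07). These calls used the preset correlation, and the list lost its call with each library clustered on its own (0.732). The 16 genes had a median log2 fold change of -0.77 in the deeper cluster, whose barcodes helped to choose them, and calls fell from 17 to 5 at 400 UMIs or more. RNA of monocytes and neutrophils in lymphoid barcodes stays open too. The same genes had a median of -0.36 in NK-like and B-like cells, with 26 of 29 values below 0, against -1.21 in T-like cells. An SE of 0.06 was taken over these 29 values, where a gene can count once per class, and not over donors. Of the 16 genes, 15 were more abundant in monocyte-like or neutrophil-like cells than in T-like cells. Neither a difference of EoE T cells themselves nor the mix of the T-like clusters was tested as the source.

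Interferon-response genes were higher in EoE neutrophil-like and monocyte-like cells. In neutrophil-like cells the values are consistent with a single library as the source, since the median log2 fold change was -0.007887 without EoE replicate 1. In monocyte-like cells it was 0.3296 without that library and the list still passed (camera adjusted p = 0.00778, and 0.818 with an estimated correlation), so a single library and a difference of the group cannot be told apart with 2 EoE libraries left. Of those 2, EoE replicate 2 had a summed list of 3790 CPM and EoE replicate 3 of 2275, against 2491 to 2832 in the controls. RNA of interferon-high neutrophils in monocyte-like barcodes was argued against for EoE replicate 1 alone: in that library the excess of 22 interferon genes over the control mean in monocyte-like cells was 0.405 of that in neutrophil-like cells (lower quartile 0.285), where neutrophil markers stood at 0.116, a ratio of 3.487. For the other EoE libraries this source stays open, as does a difference between the donor groups.

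HLA-DQB1 was higher in EoE cells. Its log2 fold change exceeded the median of other class II genes by 1.462 in neutrophil-like, 2.32 in monocyte-like and 1.55 in B-like cells. Donor variants that change how many reads match the reference may therefore contribute, as may expression itself, and the files hold no reads to separate them. No variant was examined.

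Splits of the 6 libraries into groups of 3 number 10, which is too few for a share under 0.05. Gene counts as large as the real one, that one included, came from 10 splits for eosinophil-like cells (real 0, highest other 0), 10 for neutrophil-like (0 and 0), 2 for monocyte-like (1 and 1), 1 for T-like (17 and 1), 2 for NK-like (7 and 7), 10 for B-like (0 and 1), 1 for all barcodes summed (2 and 0) and 5 for the interaction of group and class (2 and 8). Counts of gene lists as large came from 2 splits for eosinophil-like (5 and 6), 10 for neutrophil-like (4 and 8), 3 for monocyte-like (6 and 7), 2 for T-like (8 and 11), 3 for NK-like (3 and 5) and 6 for B-like cells (3 and 4). For the interaction, the split with 8 genes set control replicate 1, EoE replicate 1 and EoE replicate 3, the 3 libraries with the fewest UMIs (1539499, 2120373 and 1306063), against the others. That split follows depth, and its genes were not examined.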

How the results depend on the processing

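The deeper T-like cluster on its own and RLE scaling for the gene lists were alternatives chosen after the data were seen. Of 2347 alternative values for 127 pairs of a gene and a class, 1999 kept their direction and side of the threshold. A further 219 kept the direction and lost the call, 121 kept it and gained a call, and 8 reversed. Many of these genes were named because their groups did not overlap, which by itself leaves little room for a reversal. A gene that passed in neither fit counts among the 1999, so these counts do not measure stability. NK-like cells gave no value for genes or lists with each library clustered on its own, since too few libraries held enough of them. For the values below the cause was not tested, except that fewer libraries or fewer barcodes follow from the alternative itself. The labels give no pairing of donors by replicate number. Same-numbered libraries of the groups correlated across genes between -0.0444 and 0.0808 after centring, and genes are not independent replicates. The same-numbered library was still the best partner for replicates 1, 2 and 3 in T-like cells. It was so for replicate 1 alone in monocyte-like, NK-like and B-like cells and all barcodes summed, and for none in eosinophil-like and neutrophil-like cells. A link by number is therefore not excluded.

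Leaving out 1 library at a time, the difference in share ran from -0.3491 to 24.53 points for neutrophil-like and from -2.028 to 2.485 for B-like cells. Genes called ran from 0 to 15 in monocyte-like, 1 to 132 in T-like, 0 to 12 in NK-like and 0 to 10 in B-like cells, 0 to 6 in all barcodes summed and 0 to 5 for the interaction of group and class. Gene lists passing ran from 1 to 5 in eosinophil-like, 1 to 9 in neutrophil-like, 3 to 9 in monocyte-like, 5 to 10 in T-like, 1 to 5 in NK-like and 1 to 4 in B-like cells. The log2 fold change of MCL1 in eosinophil-like cells ran from -0.01962 to 0.7025, the log2 fold change of DUSP6 in eosinophil-like cells from -0.1685 to 1.049 and the log2 fold change of IFIT3 in eosinophil-like cells from -0.1145 to 1.413. The log2 fold change of IFIT3 in neutrophil-like cells ran from -0.2083 to 1.205 and the log2 fold change of FOS in monocyte-like cells from -0.02293 to 1.45.

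With each library clustered on its own, genes called were 2 in monocyte-like and 5 in T-like cells and 0 for the interaction, lists passing were 7 in neutrophil-like cells, the difference in monocyte-like share was 0.9365 points, the log2 fold change of S100A9 in T-like cells was 0.8985 and the log2 fold change of RPLP2 in T-like cells was -0.007311. That setting lacked control replicate 1 and EoE replicate 3 for eosinophil-like cells and the interaction. It lacked EoE replicate 1 for T-like cells and control replicate 1 for B-like cells. With no barcode removed as a doublet, genes called were 1 in neutrophil-like and 3 in B-like cells and 0 for the interaction, and lists passing were 1 in eosinophil-like and 1 in B-like cells. At Scrublet's automatic threshold, they were 9 in T-like and 3 in NK-like cells and 0 for the interaction, with 3 lists in eosinophil-like and 1 in B-like cells. At a Leiden resolution of 2.0, they were 37 in T-like and 1 in B-like cells and 0 for the interaction, with 3 lists in eosinophil-like cells. At a Leiden resolution of 0.5, they were 30 in T-like, 0 in NK-like and 2 in B-like cells and 0 for the interaction. At 400 UMIs or more, they were 5 in T-like, 2 in NK-like and 4 in B-like cells, 1 in all barcodes summed and 0 for the interaction, with 2 lists in T-like and 1 in B-like cells. At 100 UMIs and 50 genes or more, they were 2 in monocyte-like, 45 in T-like and 4 in NK-like cells and 1 for the interaction, with 1 list in B-like cells. With no mitochondrial limit, they were 0 in NK-like cells, 0 in all barcodes summed and 0 for the interaction. The settings with no barcode removed as a doublet and with Scrublet's automatic threshold differ by 0 to 4 barcodes per library. Their results thus differ on nearly the same barcodes.

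With a correlation estimated per list, lists passing were 0 in eosinophil-like, 0 in neutrophil-like, 0 in monocyte-like, 0 in T-like, 0 in NK-like and 0 in B-like cells. With the replicate number as a block, genes called were 1 in neutrophil-like, 13 in monocyte-like, 109 in T-like and 0 in NK-like cells and 0 in all barcodes summed, lists passing were 2 in eosinophil-like cells, and the log2 fold change of DUSP6 in eosinophil-like cells was -0.1198. With no filter beyond 1 count, genes called were 78 in neutrophil-like, 88 in monocyte-like, 117 in T-like, 3 in NK-like and 2 in B-like cells, 4 in all barcodes summed and 0 for the interaction. With DESeq2 they were 3 in monocyte-like, 31 in T-like and 1 in NK-like cells and 6 in all barcodes summed. With robust fitting they were 0 in monocyte-like and 2 in B-like cells. With RLE scaling, lists passing were 3 in eosinophil-like cells. In the deeper T-like cluster alone, T-like genes called were 2 and lists passing 4. Sums of the eosinophil-like class started at 6058 UMIs. C1ORF162 and P2RY14 were followed through the alternatives by their count only.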

Other observations

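The list tests over all barcodes and the share of basophil-like cells were added to the planned comparisons after the data were seen, while shares over named leukocytes were planned. Summed over all kept barcodes, 9 lists passed at the preset correlation, none with an estimated correlation (smallest adjusted p = 0.642). Interferon-response genes were higher for 23 of 24 (median log2 fold change 1.18, camera adjusted p = 4.69e-07), with a median of 0.10 without EoE replicate 1 (adjusted p = 0.472). Neutrophil granule proteins were higher for 3 of 3 (median 1.07, adjusted p = 0.00431), of which 2 rose adjusted over the list alone. Cytotoxic effectors were lower for 10 of 12 (median -0.37, adjusted p = 0.000706), of which 3 fell adjusted over the list alone, and the call was lost without EoE replicate 1 (0.0735). These sums move with the shares of the classes.

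Basophil-like cells made up 1.77% ± 0.81 of EoE and 2.46% ± 2.06 of control barcodes (SD, n = 3 each; exact permutation p = 0.8). Over barcodes of named leukocytes, the share of T-like cells was 15.9% ± 10.03 in EoE and 32.3% ± 9.57 in control libraries (exact permutation p = 0.1, the smallest possible), and that of monocyte-like cells 9.59% ± 1.58 and 13.7% ± 1.96 (exact permutation p = 0.1).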
